A study of Mus musculus with 32 samples.

How the data were processed

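Bulk RNA sequencing libraries were prepared with the SMART-Seq v4 low-input kit from 500 sorted cells each. The cells came from spleens of C57BL/6 mice aged 12 weeks, taken 14 days after intraperitoneal immunization with NP-CGG in alum, a hapten coupled to chicken gamma globulin that raises a T cell dependent antibody response. The mice carried a cre recombinase, with or without aPIK3CD, which the series describes as activated PIK3CD signalling. The 32 libraries form 8 groups of 4 replicates, naive B cells, dark zone B cells, light zone B cells and plasma cells of WT and of aPIK3CD mice. Replicates were grouped by title, which the descriptions and the names of the count columns follow. In the 4 libraries titled aPIK3CD replicate 1, 1 per population, the genotype field reads WT, so these libraries were also counted as WT, or left out, as alternatives. Xist counts were present in 32 libraries and counts of the Y-linked genes examined in 0.

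The deposited table holds raw counts per gene, whole numbers for 53465 Ensembl genes in 32 columns, all of which were used. Per the labels, the authors used STAR 2.4.2a, HTSeq and Picard, the last 2 without a version and without a stated role. The genome build is not given in the sources used here, and no coordinates are reported. Of the gene identifiers, 53274 were found in the GENCODE M21 annotation, which served only for exon length and GC content. Without a name were 3433 genes (0.173% of counts) and 107 names occurred more than once, so genes were matched by identifier. Counts per gene were bounded near 2 per exonic base, the highest being 2.07 for Igkv5-39 in any library. Igkc, with 532 exonic bases, reached at most 1044 counts, and Ighm, with 1886 exonic bases, at most 3484. Whether duplicate reads had been removed is not stated.

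Total counts ranged from 1965329 to 2820830 in naive B cells, from 902088 to 1835558 in light zone B cells, and from 473149 to 788999 in plasma cells. In dark zone B cells they ranged from 1154809 to 1941224, except in WT replicate 3 with 25797. Intervals and floors given for counts cover counting error only, since reads without molecular identifiers are not independent molecules. Where every library of a group had 0 counts, folds are lower bounds against a floor of 3 counts over the group.

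The following was chosen before the data were examined, unless stated otherwise. Each comparison of 2 groups was fitted alone with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter (minimum count 10, minimum total count 15) and the two-sided quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p below 0.05 passed the test. Comparisons were aPIK3CD against WT in each population, light zone against dark zone in each genotype, and plasma cells against naive B cells in WT. Interactions were tested in a single fit of all 32 libraries, for the difference of the genotype effect between the zones and, with 3 degrees of freedom, among the 4 populations. Values in CPM are counts relative to TMM-scaled library sizes and are given as mean ± SD of 4 libraries, and log2 fold changes with their standard error (SE). In edgeR fits this SE was not estimated directly. It was taken as the absolute log2 fold change divided by the square root of the F statistic. For 39 gene lists, camera of limma 3.58.1 was run on voom values with a preset inter-gene correlation of 0.01, over lists with at least 5 tested members, and again with the estimated correlation. The fry test, which asks whether the genes of a list move on balance one way, was also run, and a two-sided exact permutation test of each list's mean log2 CPM was added after seeing the data. List members passing are counted adjusted over all genes tested and adjusted over the list alone. Of the list symbols, 9 were not in the table.

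Named genes are Pik3cd and, in each genotype comparison, the 12 genes in each direction with the largest log2 fold change among those past the threshold, with a mean CPM of at least 10 in the higher group and no overlap between the groups. In comparisons of populations 5 per direction are named. Predicted genes and immunoglobulin and T cell receptor segments are not named by this rule. Up to 4 members with the smallest p are named from a list described, and 6 genes from each interaction. 1 gene is not reported here. Genes outside this rule are said to have been chosen after their values were seen.

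Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, no filter on low counts, removal of immunoglobulin and T cell receptor genes before normalization, thinning to the smallest total, the replicate number as a block, a single fit over all groups, the other grouping of aPIK3CD replicate 1, and leaving out each replicate in turn. For the interaction among populations DESeq2 was run with its likelihood ratio test. A correction for position saturation, removal of exon length or GC trends by loess, log2 total count as a covariate and the interactions without the dark zone library of WT replicate 3 were added after seeing the data. Depth models of lists were first run on summed shares and then, after these were seen, on mean log2 CPM, which is reported. For the place of the library titled aPIK3CD replicate 1, a looser bound drawn up after its value was seen was discarded. The comparison of single libraries with their group was first run on plain CPM, then on TMM-scaled CPM, and then extended to more of the genes named here. The pipeline was tested on simulated data with the spread of the real libraries. Of 100 genes changed 2-fold, 46 were recovered in plasma cells, 48 in dark zone, 60 in light zone and 41 in naive B cells, and of 100 changed 4-fold, 95, 85, 88 and 78. Of the calls, 5 of 146, 11 of 144, 11 of 159 and 6 of 125 were false, and 16 of 166 for light zone against dark zone in WT. False calls were 8 of 151 for the zones in aPIK3CD and 10 of 129 for plasma cells against naive B cells. For the interactions between zones and among populations 14 and 15 of 100 genes were recovered at 2-fold and 46 and 46 at 4-fold. Of the interaction calls 2 of 62 between zones and 7 of 68 among populations were false. A list raised 1.3-fold in simulated plasma cells was called in 10 of 10 datasets, with 0 calls of other lists. Genes were simulated independently of each other, so this does not test false calls of lists whose genes are correlated.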

Results

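Gene expression was measured in naive B cells, germinal centre B cells of the dark and light zones and plasma cells sorted from the spleens of immunized mice with activated PIK3CD (aPIK3CD) or without it (WT). Each of the 8 groups held 4 libraries, and the total gene count per library was between 473149 and 2820830 in 31 libraries and 25797 in dark zone WT replicate 3. Plasma cell totals were 473149 to 704361 in WT and 652722 to 788999 in aPIK3CD. The series asks how activated PIK3CD signalling alters the transcriptome of each population.

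**Figure D1:**
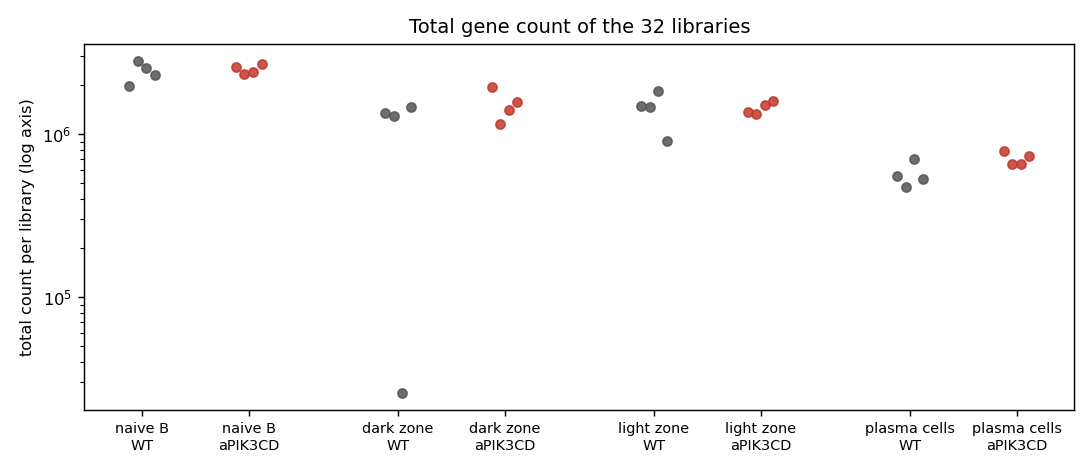
Total gene count of each library (vertical log axis) by population and genotype, with 1 point per library and 4 libraries per group. Dark zone WT replicate 3, at 25797 counts, lies far below the other 31 libraries.

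Pik3cd (ENSMUSG00000039936) encodes the catalytic subunit p110-delta of the leukocyte phosphoinositide 3-kinase. In plasma cells it measured 64.5 ± 17.2 CPM (SD, n = 4) in aPIK3CD and 103.3 ± 11.7 in WT (log2 fold change -0.68, SE 0.20, edgeR adjusted p = 0.0733). In naive B cells it measured 147.7 ± 51.2 and 233.7 ± 115.7 CPM (-0.67, SE 0.32, edgeR adjusted p = 1). In dark zone cells the values were 217.8 ± 47.7 and 194.6 ± 31.9 CPM (0.08, SE 0.17, edgeR adjusted p = 0.938), and in light zone cells 172.3 ± 30.8 and 184.4 ± 14.8 CPM (-0.10, SE 0.15, edgeR adjusted p = 0.894). In none of these 4 populations did Pik3cd RNA pass the test.

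In plasma cells, Cd93 (ENSMUSG00000027435), a surface receptor of long-lived plasma cells, fell in aPIK3CD to 82.6 ± 5.36 CPM from 256 ± 31.97 in WT (SD, n = 4; log2 fold change -1.63, SE 0.14, edgeR adjusted p = 0.000135). Osbpl3 (ENSMUSG00000029822), an oxysterol-binding protein family member, fell to 6.51 ± 0.291 from 58.8 ± 12.7 CPM (-3.14, SE 0.33, edgeR adjusted p = 0.000735). Il10, an anti-inflammatory cytokine, rose to 66.2 ± 9.21 from 23.5 ± 3.52 CPM (1.49, SE 0.24, edgeR adjusted p = 0.0172). Nox1, the catalytic subunit of an NADPH oxidase, rose to 24.0 ± 2.10 from 2.24 ± 3.35 CPM (3.07, SE 0.59, edgeR adjusted p = 0.0229).

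Of 7771 genes tested in plasma cells, 154 rose and 95 fell in aPIK3CD, and 33 and 36 of them by more than 2-fold. In a single fit over all 8 groups 72 rose and 75 fell. The other genes named among the rises were Cyb561a3 (log2 fold change 1.78), Daglb, a diacylglycerol lipase (1.75), Cnpy3, an endoplasmic reticulum chaperone of Toll-like receptors (1.69). They also included Ppp2r1b, a scaffold subunit of protein phosphatase 2A (1.62), and Papss1, which makes the sulfate donor PAPS (1.56). Gpx3, an extracellular glutathione peroxidase, changed by 1.55, Pqlc1 by 1.45, Amigo2, a cell adhesion protein, by 1.39, Ankrd54 by 1.35 and Maged1 by 1.29. Among the falls were Crisp1, a cysteine-rich secretory protein (-3.50), Itpr1, the inositol trisphosphate receptor calcium channel (-2.46). Itih5 (-2.29), Susd3 (-1.76), Ctdsp1, a phosphatase of the RNA polymerase II tail (-1.75), and Sh2d2a, a signalling adaptor (-1.69), fell as well. Atp1b1, a subunit of the sodium pump, had a value of -1.60, Ccnk, cyclin K, -1.57, Satb1, a chromatin organizer, -1.48, and Gxylt1 -1.42. The SE of these log2 fold changes lay between 0.23 and 0.55. Each of these genes was higher or lower in all 4 aPIK3CD libraries than in all 4 WT libraries, which the naming rule required, so their separation is no further support. Of the 249 genes, 239 were separated in this way, as were 14.9% of all genes tested, where chance gives 2.86%. The plasma cell regulators Prdm1, Irf4 and Xbp1, chosen after their values were seen, had log2 fold changes of -0.03, -0.15 and -0.0015 (edgeR adjusted p = 0.909, 0.497 and 0.996).

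The count of 249 rested on single libraries and on the method. It was 694 without a filter on low counts, 625 without immunoglobulin and T cell receptor genes, 538 with DESeq2, 147 in a single fit over all groups and 77 with the replicate number as a block. It was 41 without WT replicate 1, 15 without WT replicate 2, 243 without WT replicate 3, 223 without WT replicate 4, 128 without aPIK3CD replicate 1, 63 without replicate 2, 17 without replicate 3 and 33 without replicate 4, and 2 with aPIK3CD replicate 1 counted as WT. With libraries thinned to the smallest total it was 217. With log2 total count as a covariate, added after seeing the data, it was 4, but the aPIK3CD libraries were deeper, so this covariate overlaps with genotype. In genotype comparisons the replicate block joins libraries of different mice. In plasma cells the deviations of these pairs from their group means correlated at 0.0245, 0.0164, -0.0186 and 0.0127, so no pairing was seen. Of the 38 genes the naming rule gave in plasma cells, 38 lost their call with aPIK3CD replicate 1 counted as WT and 36 with the covariate. Their log2 fold changes kept their sign under all alternatives, some with little change, such as Osbpl3 (-3.46 to -2.81), Edem1 (0.29 to 0.39) and Ctsc (0.53 to 0.68), others with more, such as Igha (-0.74 to -0.22). Without WT replicates 1 to 4 the losses were 25, 35, 4 and 8 genes, and without aPIK3CD replicates 1 to 4 they were 13, 22, 33 and 29. Daglb and Sh2d2a lost their call in 8 of 8 fits that left out 1 replicate, Cyb561a3, Ankrd54, Ctdsp1, Gxylt1, Ccnk and Gpx3 in 6, and Nox1 (log2 fold change 1.68 to 4.78 over the alternatives), Satb1, Ppp2r1b and Susd3 in 5. Cd93 and Osbpl3 lost it in 0 of these 8 fits and kept it with the covariate, but lost it with aPIK3CD replicate 1 counted as WT (adjusted p = 0.203 and 0.198, over alternatives from 3.92e-16 and 4.48e-11), and Cd93 also in a single fit over all groups.

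**Figure D2:**
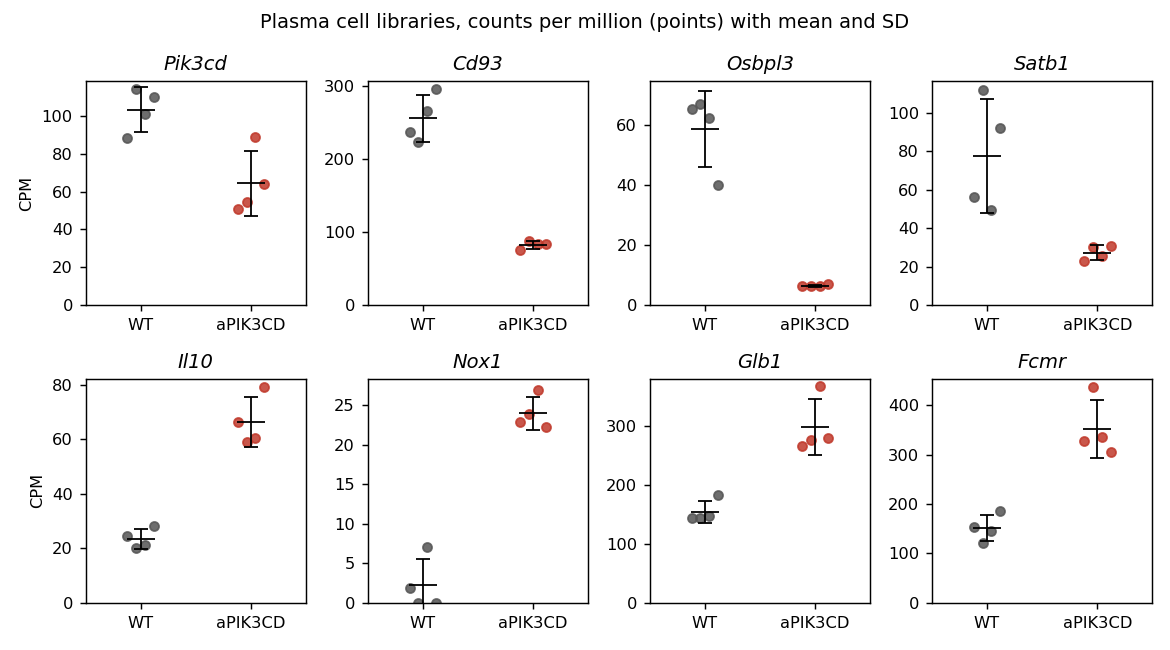
CPM (vertical axes from 0) of Pik3cd, Cd93, Osbpl3, Satb1, Il10, Nox1, Glb1 and Fcmr in the plasma cell libraries, with 1 point per library and the mean and SD of each genotype (n = 4). For every gene shown except Pik3cd, the 4 aPIK3CD libraries lie apart from the 4 WT libraries. For Cd93, Osbpl3, Satb1, Il10 and Nox1 the naming rule required this.

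Of 39 genes of lysosomes tested in plasma cells, 7 rose and 0 fell over all genes, and 15 rose and 0 fell adjusted over the list alone. Their median log2 fold change was 0.36 (limma camera adjusted p = 1.48e-07; adjusted p = 0.479 with an estimated correlation). Glb1, the lysosomal beta-galactosidase, rose to 298 ± 47.5 from 154 ± 18.6 CPM (0.95, SE 0.15). The proton pump genes Atp6ap1 (0.65, SE 0.13) and Atp6v1h (0.69, SE 0.13) rose, and so did Ctsc, cathepsin C (0.60, SE 0.14). Of 8 fits that left out 1 replicate, Glb1 lost its call in 2, Atp6ap1 in 5, Atp6v1h in 4 and Ctsc in 6. The mean log2 CPM of the list was higher by 0.335 (exact permutation p = 0.0286, the smallest this design allows, adjusted p = 0.108 over 34 lists). The fry test gave an adjusted p of 0.0376. Summed CPM of monocyte, macrophage and neutrophil markers was 542 ± 237 in aPIK3CD and 373 ± 198 in WT.

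Of the MYC target and ribosome biogenesis list 0 of 36 genes passed over all genes and 0 adjusted over the list alone. Its median was 0.24 (limma camera adjusted p = 0.045; adjusted p = 0.479 with an estimated correlation). Its members Srm, spermidine synthase, and Nop56, a nucleolar protein, had values of 0.45 and 0.62. Of 27 genes of the ATF4-CHOP stress response 1 rose and 0 fell, and 9 rose and 3 fell adjusted over the list alone. That list had a median of 0.25 (limma camera adjusted p = 0.045; adjusted p = 0.548 with an estimated correlation). The gene that rose was Chac1, a glutathione-degrading enzyme (0.98, SE 0.22), which lost its call in 8 of 8 fits that left out 1 replicate.

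Mitochondrially encoded transcripts were lower, 4 of 9 over all genes and 8 adjusted over the list alone. They had a median of -0.57 (limma camera adjusted p = 4.36e-07; adjusted p = 0.479 with an estimated correlation). They included the ribosomal RNA genes mt-Rnr1 (-1.07, SE 0.20) and mt-Rnr2 (-0.76, SE 0.13) and mt-Nd4 of complex I (-0.57, SE 0.13). Of the 8 fits without 1 replicate, mt-Rnr1 and mt-Rnr2 lost their call in 3 each and mt-Nd4 in 7, and mt-Nd4 also after removal of the exon length or the GC trend. Of 71 nuclear genes of oxidative phosphorylation 1 rose and 0 fell, and 2 rose and 11 fell adjusted over the list alone. The median there was -0.29 (limma camera adjusted p = 7.21e-06; adjusted p = 0.535 with an estimated correlation). The complex I gene Ndufs1 rose (0.75, SE 0.14; call lost without 1 replicate in 4 of 8 fits), while Ndufa4 had a value of -0.53 (edgeR adjusted p = 0.0502). Of 51 cytosolic ribosomal protein genes 0 passed over all genes and 0 adjusted over the list alone. Their median was -0.35 (limma camera adjusted p = 5.64e-07; adjusted p = 0.548 with an estimated correlation). Rpl14 was at -0.52 and Rps15 at -0.54. Of 10 immunoglobulin constant genes 1 fell over all genes and 6 adjusted over the list alone. Their median was -0.36 (limma camera adjusted p = 0.00891; adjusted p = 0.548 with an estimated correlation). The gene that fell was Igha, the IgA heavy chain, at 2905 ± 369 against 4415 ± 780 CPM (log2 fold change -0.60, SE 0.12). It lost its call with log2 total count as a covariate (-0.22), in 5 of 8 fits without 1 replicate (WT 1 and 2, aPIK3CD 1, 3 and 4), in a single fit over all groups and with aPIK3CD replicate 1 counted as WT. It kept it after a correction for the bound on counts per exonic base (-0.68), of which it had at most 0.9. Other constant genes lay nearer that bound, with Igkc and Ighm at up to 1.96 and 1.85 counts per exonic base in any library. Their counts had little room to rise with depth, so an effect of the bound on the list is not excluded. The aPIK3CD plasma cell libraries were also deeper, with a mean total of 708454 ± 66597 counts against 565426 ± 98866 in WT (SD, n = 4). With log2 total count as a covariate, added after seeing the data, 5 lists passed in place of 10, and the median of the immunoglobulin constant list became 0.04.

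Plasma cell identity and survival genes went both ways, with 2 of 34 up and 2 down over all genes and 4 up and 7 down adjusted over the list alone. The list's median was -0.16 (limma camera adjusted p = 0.045; adjusted p = 0.535 with an estimated correlation). Fut1, a fucosyltransferase, rose (0.79, SE 0.16), as did Edem1 of endoplasmic reticulum degradation (0.33, SE 0.07), while Cd93 and the costimulatory receptor Cd28 (-0.86, SE 0.20) fell. Leaving out 1 replicate ended the call of Cd28 in 7 of 8 fits, of Edem1 in 6, of Fut1 in 5 and of Cd93 in 0. Of 27 PI3K-AKT-mTOR pathway components 0 passed over all genes and 1 rose and 3 fell adjusted over the list alone. This pathway list had a median of -0.20 (limma camera adjusted p = 0.045; adjusted p = 0.479 with an estimated correlation). Its members Gsk3b, a kinase that AKT inhibits, and Foxo1, a transcription factor that AKT excludes from the nucleus, had values of -0.85 and -0.55 (edgeR adjusted p = 0.0572 and 0.08). Of 6 dendritic cell markers 0 passed over all genes and 4 fell adjusted over the list alone. These markers had a median of -0.42 (limma camera adjusted p = 0.045; adjusted p = 0.479 with an estimated correlation), with Ccr9 at -1.69 and Bst2 at -0.56. Over all counts, Cst3 and Bst2 were at 974.3 and 251 CPM in WT plasma cells, against 207.8 and 67.31 in WT naive B cells. Siglech was at 0.4738 CPM in WT plasma cells and 92.59 in WT naive B cells. The list therefore cannot be read as a measure of dendritic cells in plasma cell libraries. Of 34 lists tested in plasma cells 10 passed, 3 upwards and 7 downwards, and 0 passed with an estimated correlation. The fry test called 2, the lysosome list and the glycolysis list.

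**Figure D3:**
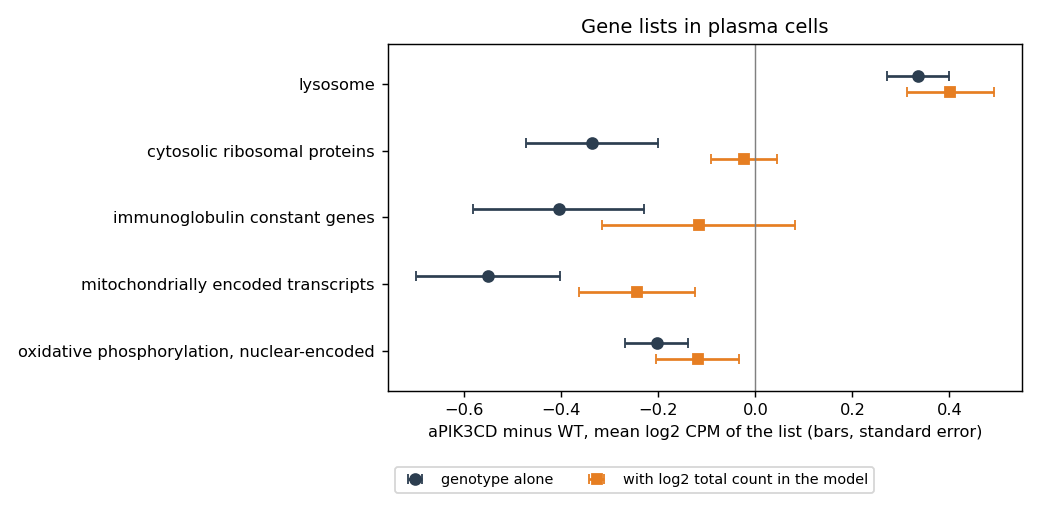
Difference between aPIK3CD and WT plasma cells in the mean log2 CPM of 5 gene lists (horizontal axis, with standard error, 4 libraries per genotype), from genotype alone (circles) and with log2 total count in the model (squares). The lysosome list stays at 0.335 and 0.402, while the ribosomal protein list goes from -0.337 to -0.0227.

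In dark zone B cells 2 of 9539 genes passed, and both were chosen for naming after their values were seen. Ighv8-8, an immunoglobulin heavy chain variable segment, was at 18.3 ± 6.47 CPM in aPIK3CD and 0.346 ± 0.692 in WT (log2 fold change 4.98, SE 0.80). The long noncoding RNA A630023P12Rik was at 12.9 ± 4.88 and 62.3 ± 30.7 CPM (-2.41, SE 0.39). Each had an edgeR adjusted p of 0.0147 and was separated in all 4 libraries. The WT value of Ighv8-8 rests on 2 counts in 1 library, and WT replicate 3, with 25797 counts in all, is too shallow for its 0 to tell. At an unadjusted p below 0.05 there were 715 genes. The count was 0 without WT replicate 3, the library of 25797 counts, and 0 with aPIK3CD replicate 1 counted as WT. DESeq2 called 1 gene and limma voom 0. It was 80 without a filter on low counts, 53 with the replicate number as a block and 4 in a single fit over all groups. It was also 1 without WT replicate 1, 0 without WT replicate 2, 3 without WT replicate 4, 0 without aPIK3CD replicate 1 and 10 without aPIK3CD replicate 2.

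Of 32 gene lists tested in the dark zone 9 passed, 7 upwards and 2 downwards, although 0 of their members passed over all genes. For G1/S and DNA replication 2 of 41 genes rose adjusted over the list alone. Their median log2 fold change was 0.17 (limma camera adjusted p = 0.002; adjusted p = 0.494 with an estimated correlation). In it were the replicative helicase gene Mcm2 at 0.52 (SE 0.15) and the licensing factor gene Cdc6 at 0.71 (SE 0.20). Of 23 genes of the germinal centre identity list 1 rose adjusted over the list alone. The median of that list was 0.12 (limma camera adjusted p = 0.0205; adjusted p = 0.386 with an estimated correlation; fry adjusted p = 0.0204). Among its genes were Basp1 at 0.67 and the glycosyltransferase gene Gcnt1 at 0.82. For the MYC target list of 41 genes the median was 0.16 and 0 rose adjusted over the list alone (limma camera adjusted p = 0.00421; adjusted p = 0.453 with an estimated correlation). The ribosome biogenesis gene Ppan was at 0.67. For mTORC1 signalling, with 61 genes, the median was 0.10 and 1 rose adjusted over the list alone (limma camera adjusted p = 0.0155; adjusted p = 0.688 with an estimated correlation). Edem1 was at 0.56.

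The immediate early and dissociation stress list of 13 genes had 1 gene that rose adjusted over the list alone. Its median was 0.35 (limma camera adjusted p = 0.00687; adjusted p = 0.386 with an estimated correlation). Its first member was the heat shock gene Hspa1b at 1.96 (SE 0.48). The NF-kB target list of 26 genes had a median of 0.16 and 0 rose adjusted over the list alone (limma camera adjusted p = 0.00517; adjusted p = 0.386 with an estimated correlation). The adhesion receptor gene Icam1 was at 0.97. The cholesterol biosynthesis list of 24 genes had a median of 0.23 and 0 rose adjusted over the list alone (limma camera adjusted p = 0.0482; adjusted p = 0.386 with an estimated correlation). The sterol sensor gene Insig1 was at 1.01. Lower were the cytosolic ribosomal proteins, with a median of -0.22 over 73 genes, 0 passing adjusted over the list alone (limma camera adjusted p = 0.000319; adjusted p = 0.763 with an estimated correlation). Rpl27a was at -0.44. The 73 oxidative phosphorylation genes had a median of -0.19, with 0 passing adjusted over the list alone (limma camera adjusted p = 2.19e-06; adjusted p = 0.688 with an estimated correlation). The complex I gene Ndufa8 was at -0.47. With log2 total count as a covariate, without WT replicate 3, the ribosomal list had a median of -0.05 and lost its call, and the oxidative phosphorylation list one of -0.12 and kept it. Within genotypes the 2 lists changed by -0.553 ± 0.0458 and -0.297 ± 0.144 per doubling of the total (SE). Without aPIK3CD replicate 1, the deepest dark zone library, the ribosomal list lost its call too (-0.08). Without WT replicate 3, 8 lists passed, without WT replicate 2, 5 lists, and with aPIK3CD replicate 1 counted as WT, 1 list.

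In light zone B cells 0 of 9860 genes passed in edgeR, with 654 at an unadjusted p below 0.05, 7 called by DESeq2 and 1 by limma voom. Genes of the interferon response with small unadjusted p, chosen after their values were seen, were the transcription factor gene Irf1 (log2 fold change 0.82, SE 0.16, edgeR adjusted p = 0.307), the class I gene H2-Q7 (0.64, SE 0.14, edgeR adjusted p = 0.507) and the GTPase gene Irgm1 (0.95, SE 0.21, edgeR adjusted p = 0.507). Over the 30 genes of the interferon response list the mean log2 CPM was higher by only 0.129 (exact permutation p = 0.286, adjusted p = 0.848). The gene count was 66 without a filter on low counts, 2 in a single fit over all groups, 1 with aPIK3CD replicate 1 counted as WT and 1 without it. Of 33 lists 0 passed with camera or with fry. With camera the number was 5 without WT replicate 3, 2 without WT replicate 4, 4 without aPIK3CD replicate 2, 1 without aPIK3CD replicate 3, 2 without aPIK3CD replicate 4, 4 with the replicate number as a block and 1 with aPIK3CD replicate 1 counted as WT.

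In naive B cells 0 of 10421 genes passed in edgeR, with 319 at an unadjusted p below 0.05, and 0 passed with DESeq2 and 0 with limma voom. A single edgeR fit over all 8 groups called 8, 2 higher and 6 lower. Of 35 lists 2 passed, both downwards, with 0 members passing over all genes and 0 adjusted over the list alone. The 9 dendritic cell markers had a median log2 fold change of -0.55 (limma camera adjusted p = 0.0178; adjusted p = 0.943 with an estimated correlation). The 11 marginal zone and B-1 cell markers had a median of -0.31 (limma camera adjusted p = 0.0178; adjusted p = 0.62 with an estimated correlation). Siglech, a lectin of plasmacytoid dendritic cells, measured 34.9 ± 34.6 CPM in aPIK3CD and 93.8 ± 51.5 in WT, and the chemokine receptor gene Ccr9 3.01 ± 3.79 and 15.8 ± 19.0. Plscr1 measured 17.6 ± 4.10 and 35.8 ± 15.03 CPM, and Zbtb32, a transcriptional repressor, 7.07 ± 10.2 and 22.7 ± 8.35. Single libraries set the number of lists, which was 8 without aPIK3CD replicate 2, 0 without aPIK3CD replicate 4, 4 without WT replicate 1 and 1 without WT replicate 3.

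In the edgeR interaction test the genotype effect differed among the 4 populations for 3 of 11736 genes. Fcmr, which encodes the Fc receptor for IgM, was at 351 ± 59.0 CPM in aPIK3CD plasma cells and 151 ± 26.9 in WT plasma cells (log2 fold change 1.21, SE 0.17, edgeR adjusted p = 0.00887). It was at 837 ± 22.2 and 881 ± 120 in naive B cells, 462 ± 78.6 and 440 ± 95.7 in the dark zone and 591 ± 113 and 579 ± 70.3 in the light zone (interaction, edgeR adjusted p = 0.0164). Igkv3-4, a kappa light chain variable segment, was at 11.5 ± 6.76 CPM in aPIK3CD plasma cells and 798 ± 89.0 in WT plasma cells, and at 99.3 ± 9.99 and 101 ± 38.6 in naive B cells (interaction, edgeR adjusted p = 0.000971). Cdc6, a DNA replication licensing factor, had 1 count over the 4 aPIK3CD naive libraries and 71 counts in 3 of the 4 WT naive libraries, a ratio of 73.7 (95% counting interval 12.8 to 2950). In the dark zone it measured 191 ± 49.4 and 108 ± 21.4 CPM (interaction, edgeR adjusted p = 0.026).

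The next genes did not pass. Angptl4, an inhibitor of lipoprotein lipase, had 0 counts over the aPIK3CD naive libraries and 55 over the WT naive libraries, at least 19.0-fold lower (edgeR adjusted p = 0.0525). Gm13684 had 0 and 53 counts, at least 18.3-fold lower (edgeR adjusted p = 0.0612), and Cnpy3 had an edgeR adjusted p of 0.066. The test called 830 genes at an unadjusted p below 0.05. The count of 3 was 338 without a filter on low counts, 46 with DESeq2, 0 with aPIK3CD replicate 1 counted as WT, 1 without aPIK3CD replicate 2 and 5 without aPIK3CD replicate 3. For the difference of the genotype effect between light and dark zone 0 of 11736 genes passed in edgeR, with 383 at an unadjusted p below 0.05 and 2 called by DESeq2. It was 90 without a filter on low counts, 1 without WT replicate 2 and 2 without WT replicate 4. The 6 genes with the smallest p were Wdr4 (edgeR adjusted p = 0.0733), Gm15228, Iglv2, Upb1, Wls and Ighv8-8, the last 5 with edgeR adjusted p of 0.314 to 0.571. Wdr4, a subunit of a transfer RNA methyltransferase, measured 56.7 ± 6.00 CPM in aPIK3CD and 16.4 ± 12.1 in WT in the dark zone, and 58.5 ± 3.74 and 97.7 ± 20.5 in the light zone.

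**Figure D4:**
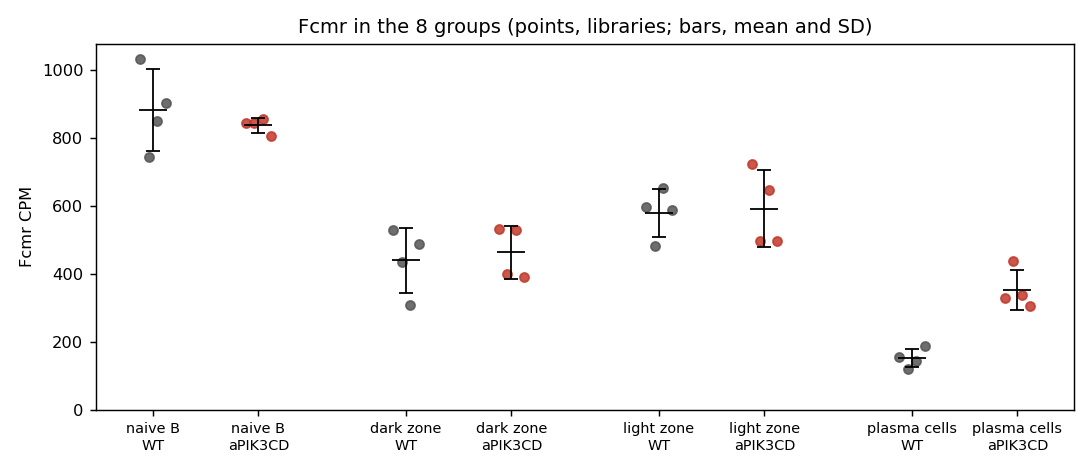
Fcmr CPM (vertical axis from 0) in the 8 groups, with 1 point per library and the mean and SD of each group (n = 4). In plasma cells the aPIK3CD libraries, at 304 to 438, lie above the WT libraries, at 121 to 186.

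In both genotypes light zone cells had more RNA of Ccnd2, cyclin D2 (log2 fold change 2.41, SE 0.25, in WT and 2.20, SE 0.28, in aPIK3CD). The same held for the transcription factor Batf (1.76, SE 0.23, and 1.76, SE 0.20) and for Myc (1.85, SE 0.25, and 1.55, SE 0.25). Dark zone cells had more RNA of the germinal centre adaptor Gcsam (-1.28, SE 0.24, and -1.46, SE 0.14) and of the kinetochore gene Cenpf (-0.70, SE 0.13, and -0.72, SE 0.11). In WT 125 of 9639 genes were higher and 121 lower in the light zone. Of these, 188 were separated in all 4 libraries, as were 9.26% of genes where chance gives 2.86%. In aPIK3CD 307 of 9798 genes were higher and 285 lower, and 558 of them were separated, as were 12.8% of genes. Over 9410 genes tested in both, 82 genes were higher in both genotypes (of 123 in WT and 300 in aPIK3CD, 3.92 if independent) and 98 lower in both (of 121 and 277, 3.56 if independent).

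The largest rises in the WT light zone were Cd70, a ligand of the TNF family, with 75 counts against 1 (ratio 54.4, 95% counting interval 9.46 to 2180), and the tetraspanin gene Cd63 with 60 counts against 2 (ratio 21.7, interval 5.76 to 184). Next came Prdm1, which encodes the plasma cell regulator Blimp-1 (log2 fold change 3.57), Trbc2, a T cell receptor constant gene (3.48), and the methyltransferase gene Smyd2 (3.37). The largest falls were Adhfe1 (-3.68), the ubiquitin ligase gene Trim2 (-3.15), Serinc5 (-1.98), Rgcc, a cell cycle regulator (-1.97), and Dnase1 (-1.77). In aPIK3CD the largest rises were Cd8b1, a T cell coreceptor gene, with 129 counts against 0 (at least 45.0-fold higher), and the receptor gene Gpr34 (4.28). After them came Zfp105 with 63 counts against 3 (ratio 22.0, interval 7.18 to 109), the interleukin 7 receptor gene Il7r (4.01) and the cytokine subunit gene Ebi3 (3.52). The largest falls there were Trim2 (-3.69), the sodium channel gene Scn11a (-2.97), Aknaos (-2.85), the globin gene Hbb-bh1 (-2.65) and Emp2 (-2.64). The SE of the log2 fold changes given lay between 0.21 and 0.75. Whether Trbc2 and Cd8b1 RNA came from T cells in the light zone sorts was not tested.

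Of 32 light zone genes 11 rose and 0 fell in WT, and 22 rose and 1 fell adjusted over the list alone. The WT median was 1 (limma camera adjusted p = 1.64e-17, and 0.0147 with an estimated correlation). In aPIK3CD 12 rose and 0 fell, and 17 and 0 adjusted over the list alone. The aPIK3CD median was 0.71 (limma camera adjusted p = 4.04e-15, and 0.03 with an estimated correlation). Of 22 dark zone genes 5 fell in WT, 11 adjusted over the list alone (limma camera adjusted p = 9.6e-14, and 0.0317 with an estimated correlation). In aPIK3CD 12 of them fell, 16 adjusted over the list alone (limma camera adjusted p = 7.31e-16, and 0.0117 with an estimated correlation). MYC targets rose, 13 of 41 in WT and 15 of 42 in aPIK3CD, and 28 and 27 adjusted over the list alone (limma camera adjusted p = 4.23e-21 and 2.01e-16, and 0.013 and 0.025 with an estimated correlation). Among them were the spermidine synthase gene Srm (1.37 and 1.22) and the nucleolar gene Gnl3 (1.03 and 0.76). Of 27 NF-kB targets 8 rose in each genotype, 13 and 11 adjusted over the list alone (limma camera adjusted p = 9.63e-13 and 5.23e-08, and 0.013 and 0.03 with an estimated correlation). Of 45 G2/M genes 8 fell in WT and 11 in aPIK3CD, 19 and 18 adjusted over the list alone (limma camera adjusted p = 9.96e-15 and 1.56e-13; adjusted p = 0.115 and 0.03 with an estimated correlation). The phosphatase gene Cdc25b was among them (-1.22 and -1.07). T cell markers were higher in the light zone, 4 of 8 in WT and 4 of 10 in aPIK3CD, 6 and 9 adjusted over the list alone (limma camera adjusted p = 0.000199 and 1.27e-07; adjusted p = 0.185 and 0.0875 with an estimated correlation). Cd3d was at 2.58 and 2.48. Monocyte, macrophage and neutrophil markers were higher too, 1 of 9 in WT and 1 of 10 in aPIK3CD, 5 and 4 adjusted over the list alone (limma camera adjusted p = 0.000779 and 0.0137; adjusted p = 0.193 and 0.4 with an estimated correlation). Their summed CPM was 98.7 ± 32.6 in dark zone and 340 ± 143 in light zone cells of WT, and 173 ± 75.3 and 435 ± 253 in aPIK3CD. At an unadjusted p below 0.05 there were 1496 genes in WT and 1908 in aPIK3CD. The WT count of 246 was 104 without dark zone replicate 1, 103 without dark zone replicate 2, 152 without light zone replicate 2, 138 without light zone replicate 3 and 419 without light zone replicate 4. The aPIK3CD count of 592 was 959 with the replicate number as a block, 346 without light zone replicate 3 and 372 without light zone replicate 4. Thinned to 25797 counts per library, the WT count was 0.

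Plasma cells of WT mice differed from naive B cells in 4842 of 9768 genes, 2479 higher and 2363 lower. Of these, 4290 were separated in all 4 libraries, as were 46.8% of genes, where chance gives 2.86%. Prg2, proteoglycan 2, had 2914 counts in plasma cells against 1 in naive B cells (ratio 12400, 95% counting interval 2230 to 490000). Higher from 0 counts in naive B cells were Tnfrsf17, the receptor BCMA (at least 1830-fold), Asns, asparagine synthetase (at least 1210-fold), Copz2, a coat protein (at least 527-fold), and Chst1, a sulfotransferase (at least 497-fold). Lower, to 0 counts in plasma cells, were Kynu, kynureninase (at least 91.4-fold), the natural killer receptor genes Klrk1 (at least 48.8-fold), Ncr1 (at least 46.0-fold) and Klra4 (at least 35.4-fold), and Lpcat2 (at least 35.1-fold). Whether the natural killer receptor RNA came from other cells in the naive B cell sort was not tested.

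Of 54 genes of endoplasmic reticulum folding and the unfolded protein response 53 rose and 0 fell in plasma cells (median log2 fold change 2.56, limma camera adjusted p = 2.49e-33, and 0.00583 with an estimated correlation), and 53 adjusted over the list alone. They included Xbp1, the transcription factor of that response (3.71, SE 0.14), and Edem1 (4.06, SE 0.15). Of 35 plasma cell identity genes 33 rose and 1 fell, 34 and 1 adjusted over the list alone. Their median was 3.84 (limma camera adjusted p = 1.36e-24, and 0.00383 with an estimated correlation), and they included Eaf2 (5.31, SE 0.19) and the transcription factor gene Creb3l2 (6.53, SE 0.23). Of 31 B cell identity genes 7 rose and 24 fell, over all genes and adjusted over the list alone. Their median was -1.63 (limma camera adjusted p = 4.95e-07; adjusted p = 0.132 with an estimated correlation). Among them were Cd22, an inhibitory coreceptor (-8.11, SE 0.33), Cr2, complement receptor CD21 (-4.97, SE 0.22), and Ciita, the class II transactivator (-6.36, SE 0.33). Of 9 natural killer cell markers 7 fell, 8 adjusted over the list alone (limma camera adjusted p = 0.00144; adjusted p = 0.104 with an estimated correlation), and their summed CPM was 560 ± 61.7 in naive B cells and 88.6 ± 35.9 in plasma cells.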

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

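The tests of depth and exon length, the counts over other splits of the samples and the choice of which gene values were compared with their group came only after the results were seen. The tests of macrophage markers and of the library titled aPIK3CD replicate 1 had their bounds set before their values were seen.

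The list of lysosomal genes had a higher mean in aPIK3CD plasma cells. With log2 total count in the model the difference of the list's mean log2 CPM was 0.402 ± 0.0889 (SE), against 0.335 ± 0.0639 without, which argues against the greater depth of the aPIK3CD libraries as the whole cause, although the list's slope per doubling of the total was 0.37 to 0.626 in the other 3 populations and -0.199 ± 0.186 in plasma cells. With log2 summed CPM of 24 monocyte, macrophage and neutrophil markers in the model (0 of them in the list, and the most abundant, Lyz2, at 216 ± 204 CPM in aPIK3CD and 138 ± 127 in WT, with no sort gate given), the difference was 0.341 ± 0.0767, which argues against macrophage RNA as the whole cause. After removal of the exon length trend of each library the list's median was 0.384, which argues against exon length. A genotype effect on lysosomal genes may stand behind the pattern as a hypothesis, found and tested in the same 8 libraries. Chance was not excluded for this list, whose adjusted exact permutation p was 0.108. That test decides little, since its smallest p is 0.0286 and the adjusted p falls below 0.05 only if many of the 34 lists reach it. The camera adjusted p ranged from 1.43e-08 to 0.479 over the alternatives. The genotype of 1 library is not settled by the bounds set.

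The ribosomal protein, immunoglobulin constant, mitochondrially encoded and oxidative phosphorylation lists were lower in aPIK3CD plasma cells, whose libraries were deeper. With log2 total count in the model the ribosomal protein difference was -0.0227 ± 0.0681, from -0.337 ± 0.137, and the immunoglobulin constant difference -0.117 ± 0.199, from -0.406 ± 0.176. Both lists fell with depth within genotypes, by -0.936 ± 0.143 and -0.859 ± 0.417 per doubling, so depth is a candidate explanation for both. In naive, dark zone (without WT replicate 3) and light zone B cells the ribosomal slopes were -0.392 ± 0.199, -0.553 ± 0.0458 and -0.59 ± 0.172. The immunoglobulin constant slopes there were -2.02 ± 0.367, -0.716 ± 0.445 and 0.119 ± 0.0921, so that list did not fall with depth in the light zone. For mitochondrially encoded transcripts (-0.244 ± 0.12, from -0.551 ± 0.148) depth and genotype cannot be told apart, since less than 50% of the difference was left but still slightly more than 2 SE from 0. Nor can they be told apart for oxidative phosphorylation (-0.119 ± 0.0859, from -0.204 ± 0.0657), whose slope of -0.252 ± 0.18 per doubling was itself within 2 SE of 0. The mitochondrially encoded list changed by -0.913 ± 0.251 per doubling in plasma cells. Its slopes in naive, dark zone (without WT replicate 3) and light zone B cells were -1.18 ± 0.216, -1.07 ± 0.0998 and -0.915 ± 0.101. Those of oxidative phosphorylation were -1 ± 0.113, -0.297 ± 0.144 and -0.444 ± 0.0551, so depth is a candidate for these lists too.

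The plasma cell library titled aPIK3CD replicate 1 has WT in its genotype field, while its description and count column follow the title. On 120 genes called without it (immunoglobulin and T cell receptor genes and genes not tested in the full comparison left out), with the WT mean at 0 and the aPIK3CD mean at 1, it lay at 0.773, where the WT libraries, placed in the same way, lay between -0.0485 and 0.379 (SD 0.187, on 12 to 217 genes) and the other aPIK3CD libraries between 0.793 and 0.897 (on 15 to 55 genes). It was thus 0.394 above the highest WT library but missed both ranges, the nearer, set by a place on 55 genes, by 0.02. Title and field thus cannot be told apart by the bounds set. Places in the other aPIK3CD libraries went down as genes went up, with 0.897 on 15, 0.803 on 30 and 0.793 on 55 genes. A miss of 0.02 on 120 genes therefore says little. The library lay nearer the aPIK3CD libraries, which argues against a WT mouse. It had 6.37 CPM of Igkv3-4, against 678 to 872 in WT and 6.39 to 20.6 in the other aPIK3CD libraries, but 0 of Igkv12-98, against 0 to 21.3 in WT and 612.7 to 774.4 in the other aPIK3CD libraries, which does not speak for WT, since aPIK3CD replicate 2 likewise had 6.39 CPM of Igkv8-34 against 523.9 to 709.1 in the others. Genes of other populations that put replicate 1 with aPIK3CD, such as Angptl4 in naive B cells (0 counts, against 3 to 20 in WT), were picked with it counted as aPIK3CD.

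Other splits of the 8 libraries of a comparison were fitted in the same way, with 35 splits each. For genes in plasma cells only the real split (1 of 35) gave 249, and the highest other gave 3. The same holds for light zone against dark zone in WT (246, 1 of 35, highest other 8) and in aPIK3CD (592, 1 of 35, highest other 0) and for plasma cells against naive B cells (4842, 1 of 35, highest other 0). These counts argue against chance, but 1 of 35 is the smallest share the design allows. The other splits also mix the 2 groups, which adds spread within each side. Chance cannot be excluded for the 2 genes in the dark zone (3 of 35, highest other 2) or the 3 genes of the interaction among populations (8 of 35, highest other 12). For gene lists chance cannot be excluded in plasma cells (10 lists, 2 of 35, highest other 12), naive B cells (2 lists, 28 of 35, highest other 9) or the dark zone (9 lists, 6 of 35, highest other 13). Where the real count was 0, every split gives as many (35 of 35) and the number of splits decides nothing, as for genes in naive B cells (highest other 0) and in the light zone (highest other 2), the interaction between zones (highest other 2) and lists in the light zone (highest other 13). Some splits called several times the real count, for lists in naive B cells and for the interaction among populations, which points to a structure of the samples or, for lists, to correlated genes under the preset correlation, and neither was tested.

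The edgeR interaction test among the 4 populations called Igkv3-4 (adjusted p = 0.000971), Fcmr (adjusted p = 0.0164) and Cdc6 (adjusted p = 0.026). Chance cannot be excluded for this count, as said above, and it was 0 with aPIK3CD replicate 1 counted as WT.

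A library far from the 3 others of its group was found in 40 of 366 groups of values examined with Dixon's ratio, of which 350 were gene values, where chance gives about 1 in 20 groups. In 5 of them (Cd70, Cd63, Ighv8-8, Prg2 and Zfp105) the other 3 libraries had 0 counts and the value rests on 1 to 3 counts, so the ratio was 1 by construction, and Lat in dark zone WT replicate 3 rests on 1 count. Dark zone WT replicate 3 had 25797 counts and 6329 genes detected, and plasma cell WT replicate 3 had 13184 genes detected.

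In plasma cells, aPIK3CD replicate 2 stood apart with Gpx3 at 46.3 and Maged1 at 110.2 CPM, replicate 3 with Glb1 at 368.2 and replicate 4 with Osbpl3 at 6.948. Among WT plasma cells, replicate 2 stood apart with Irf4 at 1123 and Upb1 at 26.91 CPM, replicate 3 with Igkv12-98 at 21.27, and replicate 4 with Glb1 at 182.2 and Tnfrsf17 at 564.7.

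In naive B cells, WT replicate 2 stood apart with Ccr9 at 44.3 and Dnajc3 at 130.6 CPM, WT replicate 3 with Kynu at 154.6 and Gm15228 at 10.96, WT replicate 4 with Prg2 at 0.3713, and aPIK3CD replicate 2 with Zbtb32 at 22.21.

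In the WT dark zone, replicate 1 stood apart with Rgcc at 325 CPM and replicate 2 with Trbc2 at 6.346 and Icam1 at 30.68. Replicate 3 did so with Gcnt1 at 0, Cenpf at 539.2 and Lat at 38.51, and replicate 4 with Cd70 at 0.6991, Cd63 at 1.398, Ighv8-8 at 1.385, Ighg1 at 365.5 and Ccnd2 at 79. In the aPIK3CD dark zone, replicate 2 stood apart with Edem1 at 329 CPM and replicate 4 with Zfp105 at 1.944, Ppan at 238.4, Fcer2a at 153.6 and Cenpf at 485.4.

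In the WT light zone, replicate 2 stood apart with Adhfe1 at 9.621 CPM, replicate 3 with Trbc2 at 40.56, and replicate 4 with Fcer2a at 209.3. In the aPIK3CD light zone, replicate 1 stood apart with Cd83 at 920.5 CPM, replicate 2 with Il7r at 17.94 and replicate 4 with Cd8b1 at 12.57.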

How the results depend on the processing

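The saturation, exon length, GC and total count alternatives, and the interactions without the dark zone library of WT replicate 3, were tests chosen only after the results were seen. Of the values of named genes under the alternatives, 510 of 821 for genotype comparisons, 1510 of 1593 for population comparisons and 146 of 176 for interactions kept their direction and side of the threshold, 311, 83 and 13 lost the call, 0, 0 and 17 gained it and 0 reversed. The lists of the genotype comparisons kept theirs in 256 of 356 values, lost the call in 98 and reversed in 2, and the cause of the changes below was not tested. The reversed medians were 0.0526 for ribosomal proteins in the dark zone with aPIK3CD replicate 1 counted as WT and 0.0358 for immunoglobulin constant genes in plasma cells with log2 total count as a covariate. The lowest camera adjusted p of a list over its alternatives lay between 2.03e-11 and 0.0442, and the highest was the one with the estimated correlation, except in plasma cells for the identity list (0.967), ribosomal proteins (0.843) and MYC targets (0.482).

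Without the filter on low counts the gene counts were 80 in the dark zone, 66 in the light zone, 694 in plasma cells, 559 for WT zones, 90 for the zone interaction and 338 for the population interaction. The DESeq2 Wald test gave 1, 7, 538, 119 and 2 for the first 5 of these, and the DESeq2 likelihood ratio test gave 46 for the population interaction. Limma voom gave 0 in the dark zone, 1 in the light zone and 480 for WT zones. Without immunoglobulin and T cell receptor genes the counts were 1 in the dark zone and 625 in plasma cells, and with thinned libraries 0 in the dark zone and 0 for WT zones. With the replicate block they were 53 in the dark zone, 77 in plasma cells and 959 for aPIK3CD zones, and for lists 0 in naive B cells and 4 in the light zone. In genotype comparisons the block joined libraries of different mice. The labels do not say whether a number marks 1 mouse across populations. In aPIK3CD zones each of the 4 pairs correlated best with its own number (residual correlations 0.178, 0.188, 0.0499 and 0.0628), a hint from the data, but in no comparison was every pair above 0.1. A single fit over 8 groups gave 8 in naive B cells, 4 in the dark zone, 2 in the light zone and 147 in plasma cells. With aPIK3CD replicate 1 counted as WT the counts were 0 in the dark zone, 1 in the light zone, 2 in plasma cells and 0 for the population interaction, and for lists 1, 1 and 5 in the same 3 populations. With log2 total count as a covariate they were 0 in the dark zone and 4 in plasma cells, and for lists 1 in naive B cells and 5 in plasma cells. Removal of the exon length trend left 5 lists in plasma cells, and the estimated correlation left 0 lists in naive B cells, the dark zone and plasma cells. Without only the dark zone library of WT replicate 3 the interactions gave 0 genes between zones and 3 among populations. In plasma cells Cd93 lost its call in 2 of 21 alternatives (edgeR, DESeq2 or limma adjusted p from 3.92e-16 to 0.203) and Osbpl3 in 1 of 20 (4.48e-11 to 0.198).

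Leaving out 1 replicate in turn gave 0 to 0 genes in naive B cells, 0 to 10 in the dark zone, 0 to 1 in the light zone and 15 to 243 in plasma cells. It gave 103 to 419 for WT zones, 346 to 629 for aPIK3CD zones, 4355 to 4770 for plasma cells against naive B cells, 0 to 2 for the zone interaction and 1 to 5 for the population interaction. The ranges for lists were 0 to 8 in naive B cells, 5 to 9 in the dark zone, 0 to 5 in the light zone and 6 to 10 in plasma cells. Changes by more than 1.5 times came in the dark zone without WT replicates 1, 2 and 3 (1, 0 and 0) and aPIK3CD replicates 1 and 2 (0 and 10), and in the light zone without aPIK3CD replicate 1 (1). In plasma cells they came without WT replicates 1 and 2 (41 and 15) and aPIK3CD replicates 1 to 4 (128, 63, 17 and 33). For WT zones they came without dark zone replicates 1 and 2 (104 and 103) and light zone replicates 2, 3 and 4 (152, 138 and 419), and for aPIK3CD zones without light zone replicates 3 and 4 (346 and 372). For the zone interaction WT replicates 2 and 4 mattered (1 and 2), and for the population interaction aPIK3CD replicates 2 and 3 (1 and 5). The lists in naive B cells numbered 4 and 1 without WT replicates 1 and 3 and 8 and 0 without aPIK3CD replicates 2 and 4, and in the dark zone 5 without WT replicate 2. Those in the light zone numbered 5 and 2 without WT replicates 3 and 4 and 4, 1 and 2 without aPIK3CD replicates 2, 3 and 4, and those in plasma cells 6 and 6 without WT replicates 1 and 2.

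Thinning to 473149 counts left 217 genes in plasma cells in place of 249, whereas log2 total count as a covariate left 4. Totals went with genotype in plasma cells (mean 708454 in aPIK3CD and 565426 in WT), so the covariate also takes up genotype differences. The count of 4 therefore cannot tell depth from genotype. Depth limits the dark zone and WT zone fits thinned to 25797 counts, which gave 0 and 0.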

Other observations

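The genes and segments described here were chosen, and their tests read, only after the results were seen. Among the 249 genes past the threshold in plasma cells, 11 were immunoglobulin or T cell receptor genes. Besides Igkv3-4 (log2 fold change -6.11, SE 0.28, edgeR adjusted p = 9.94e-08), the kappa variable segments Igkv9-129 (-3.77, SE 0.68) and Igkv4-69 (-3.73, SE 0.69), with edgeR adjusted p of 0.0214 and 0.0219, were lower in all 4 aPIK3CD libraries. Igkv12-98 was at 515 ± 350 CPM in aPIK3CD and 5.88 ± 10.3 in WT (n = 4, 6.16, SE 1.25), and Igkv8-34 at 449.9 ± 306 and 22.4 ± 26.9 (4.45, SE 0.996), both with overlap between the groups. Ighg1, the IgG1 heavy chain, measured 358 ± 106 CPM in aPIK3CD and 897 ± 356 in WT dark zone cells (-1.28, SE 0.26, edgeR adjusted p = 0.131).

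Further genes that rose in aPIK3CD plasma cells were Pld4, an endosomal nuclease (log2 fold change 1.20, SE 0.17, edgeR adjusted p = 0.00887), Grn, the lysosomal precursor progranulin (0.73, SE 0.10, edgeR adjusted p = 0.00931), the inhibitory Fc receptor gene Fcgr2b (0.64, SE 0.13, edgeR adjusted p = 0.0256) and the interleukin 5 receptor gene Il5ra (0.95, SE 0.22, edgeR adjusted p = 0.0376), each higher in all 4 libraries. Ccr10, a chemokine receptor of plasma cells that home to mucosa, was lower (-1.13, SE 0.27, edgeR adjusted p = 0.0404), with overlap between the groups.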
